A study of Homo sapiens with 6 samples.

How the data were processed

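RNA of HCT116 cells, a human colorectal carcinoma line, was sequenced in 6 libraries. The samples' titles and genotype fields placed 3 libraries in a wild-type group (WT) and 3 in a group homozygous for the N106S substitution in eIF6 (MUT). Per the labels' protocols, the mutant cells were CRISPR/Cas9-edited clones, cells were harvested below confluence, RNA was isolated by phenol-chloroform extraction and the libraries were made with a NEBNext Ultra II kit. The labels do not say whether the replicates of a group were separate cultures or separate clones, so the p-values measure only the spread between these samples, which may be technical. The series also describes ribosome profiling, which is not analysed here.

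The authors deposited 3 tables of 59251 gene symbols, one with expected counts, one with FPKM and one with TPM. The submitters' processing notes name FastQC 0.12.1, STAR 2.5.2b, RSEM 1.2.28 and DESeq2 1.42.0 and the human genome build hg38 (GRCh38), without giving their roles. The expected counts deposited by the authors were all whole numbers. Rounding them to whole numbers therefore changed none. In 177 cells a count of 0 stood beside an FPKM above 0, as whole counts made from fractional estimates would give. The deposited FPKM and TPM values, normalised by the authors for depth and transcript length, served only for alternatives. Where reads fit several near-identical genes, an estimator such as RSEM divides them, so values of single members of such families are uncertain.

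Symbols were matched to a RefSeq gene table of assembly GRCh38.p14, which gave gene class and coordinates on the same build. Of the symbols, 57842 matched directly and 370 through an older name, and 1039 did not match. Of the 1143 memberships in the gene lists, 1142 matched a row.

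Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filterByExpr (a minimum count of 10, scaled to library size, in 3 libraries, and a total of 15). Library sizes were scaled with TMM factors. MUT was compared with WT by the quasi-likelihood F-test (glmQLFit and glmQLFTest) with no covariate. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The standard error of a log2 fold change was taken as its size divided by the square root of F. The standard error of the median of a list or region is the larger of that over resampled genes and that of the difference between the groups' per-library medians. Levels are given as CPM, relative to the TMM-scaled library size, as mean ± SD over 3 libraries.

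The gene lists (42, from ribosomal proteins, ribosome assembly and mitosis to signalling targets, metabolism, stress and markers of other cell types), the tests and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members (38) were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. The same test with the correlation estimated from the data, and fry, were alternatives. Camera was also run on the genes of each of chromosomes 1 to 22 and X. The rule named EIF6, the 12 called genes with the largest and the 12 with the smallest log2 fold change among those with an average log2 CPM of at least 2, no overlap between the groups and an established symbol, and up to 4 called genes per list with the smallest p. Mitochondrial genes are given only as a list, and 1 gene that the rule takes is not reported here. Shares of counts were compared by two-sided exact permutation tests, whose smallest possible p is 0.1 with 3 against 3 libraries.

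Total counts per library ranged from 53986494 to 87656970, and from 10252501 to 21984081 without 7SL, 7SK, RPPH1 and RMRP RNA. The procedure was tested on simulated counts drawn for the same genes, library sizes and dispersions, with 200 changed genes. Of the changed genes among 14555 tested, 88.5% of those with a 4-fold change were called, 30.9% of those with a 2-fold change and 6.25% of those with a 1.5-fold change. Of 14362 unchanged genes 6 were called, and 0 changed genes were called with the wrong sign. Most simulated changes of 2-fold and 1.5-fold in single genes were thus missed, and real changes of that size may be missed too. The simulation gave all libraries the same dispersion for a gene. It therefore did not model a single library that stands apart, as MUT replicate 2 did.

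Alternatives were DESeq2's size factors in edgeR, library size alone, no low-count filter, a minimum of 1 CPM in 3 libraries, a robust fit, the replicate number as a block, the DESeq2 1.42.0 Wald test on the same filtered genes, limma-voom, limma on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1) with a minimum of 1 in 3 libraries, and leaving out each library in turn. A term for the 2 libraries with the most ribosomal RNA, a fit on the other 4 libraries, and the removal of the abundant noncoding RNAs were added after seeing the data. Counts of 2 libraries of a group differed by more than sampling noise in every pair, so no library was counted as a duplicate. Genes of chromosome Y and XIST are not reported.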

Results

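Total RNA was sequenced from HCT116 cells, a human colorectal carcinoma line, that were wild type (WT, 3 libraries) or homozygous for the N106S substitution in eIF6 (MUT, 3 libraries). eIF6 is a factor of the large ribosomal subunit that keeps it from joining the small one, and the study asks how targeting eIF6 affects ribosome pools, mitotic exit and tumour growth. The WT libraries held 87656970, 69342679 and 63951768 counts and the MUT libraries 80146608, 58935201 and 53986494. Small structural RNAs took most of them. The 7SL family, the RNA of the signal recognition particle, made up 61.8% ± 4.3 of WT and 53.97% ± 9.3 of MUT counts (SD, n = 3). Without 7SL, 7SK, RPPH1 and RMRP RNA, 16527965, 17798865 and 10252501 counts remained in WT and 15305069, 21984081 and 11094084 in MUT.

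MUT replicate 2 stood apart from the other libraries. Ribosomal RNA took 7.01% of its counts, against 0.280% and 0.306% in the other MUT libraries. WT replicate 1, at 1.77%, was also above the other WT libraries, at 0.227% and 0.418%. Across genes, which are not independent replicates, log2 CPM of MUT replicate 2 correlated with the other MUT libraries at 0.940 and 0.943, and those correlated with each other at 0.976. Counts of the 7SL pseudogene RN7SL5P reached 8179680 in MUT replicate 2, at most 58 in the other MUT libraries and at most 14666 in WT. The ribosomal protein gene RPL41 had 116276 counts there and at most 1215 in any other library, while its pseudogene RPL41P2 had 1433 there and at least 25359 elsewhere.

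EIF6 itself (chromosome 20, 35278906 to 35284772, GRCh38) was measured at 43.3, 47.9 and 47.4 CPM in the WT libraries and at 36.7, 30.7 and 35.7 CPM in the MUT libraries. The log2 fold change was -0.43 (SE 0.12). It did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.110), though it did in DESeq2's test (-0.41, adjusted p = 0.0492). Over all alternatives the adjusted p ran from 0.0492 to 0.885. The sign turned by library size alone (0.09), on the TPM scales (0.18 and 0.19) and on the FPKM scale (0.09). The median of all genes there was higher still, at 0.54, 0.36, 0.49 and 0.33. The edit substitutes an amino acid, so the transcript level does not check the genotype.

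MUT cells had more mRNA of the cell cycle inhibitor CDKN1A and other p53 target genes, of the integrins ITGB4 and ITGA3 and of the Wnt target genes DKK1 and CCND1. They had less mRNA of the neuronal-type tubulin TUBB3, the actin regulator VASP, the replication licensing factor CDT1 and the cholesterol synthesis enzymes MVD and FDFT1. TUBB3, CDT1 and MVD lie near the end of the long arm of chromosome 16, where 41 of 45 tested genes with an average log2 CPM above 0 had values below 0. Of 14808 genes tested, 283 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 146 higher and 137 lower in MUT. Of these, 105 differed by over 2-fold, 52 higher and 53 lower, and 253 were protein coding. The 3 WT and 3 MUT values did not overlap for any of the 283. Over all tested genes 26.1% did not overlap, where chance gives 10%. Leaving out 1 library gave 30 genes without WT replicate 1, 27 without WT replicate 2, 61 without WT replicate 3, 40 each without MUT replicates 1 and 3, and 442 without MUT replicate 2. The 4 libraries low in ribosomal RNA alone gave 395 genes, 220 of them among the 283, and a term for the other pair gave 407. In the fits that left out 1 library other than MUT replicate 2, the lists below held no called gene, except p53 targets in every such fit, and antigen presentation, mitochondrial ribosomal proteins, adhesion and inflammation in some. Fold changes are relative to TMM scaling. By library size alone the median of all genes lay at 0.54 on the log2 scale, and 95 of 108 called genes were higher in MUT. On the log2(TPM + 1) scale the median of all genes lay at 0.36. Values given below under these scalings are to be read against those medians, since a value above 0 there can lie below the typical gene. Of the 38 gene lists with enough tested members, camera called 5 higher and 6 lower. With an estimated correlation it called 0, with 2 at an unadjusted p below 0.05, and fry called 2. For the called lists the estimate ran from -0.0147 (cholesterol synthesis) to 0.863 (replication histones), against the preset 0.01. Of the 9 other splits of the 6 libraries into 3 and 3, camera also called replication histones in 5, 60S assembly, large-subunit ribosomal proteins and mitochondrial genome genes in 4 each, p53 targets and the respiratory chain in 3 each, 40S assembly and YAP/TAZ targets in 2 each, G1/S and replication and Wnt targets in 1 each, and cholesterol synthesis in 0. Each of these splits mixes the groups unevenly, so part of a true difference between MUT and WT remains in it. Median, mean and camera's direction differed in sign for 8 lists, 0 of them called.

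**Figure D1:**
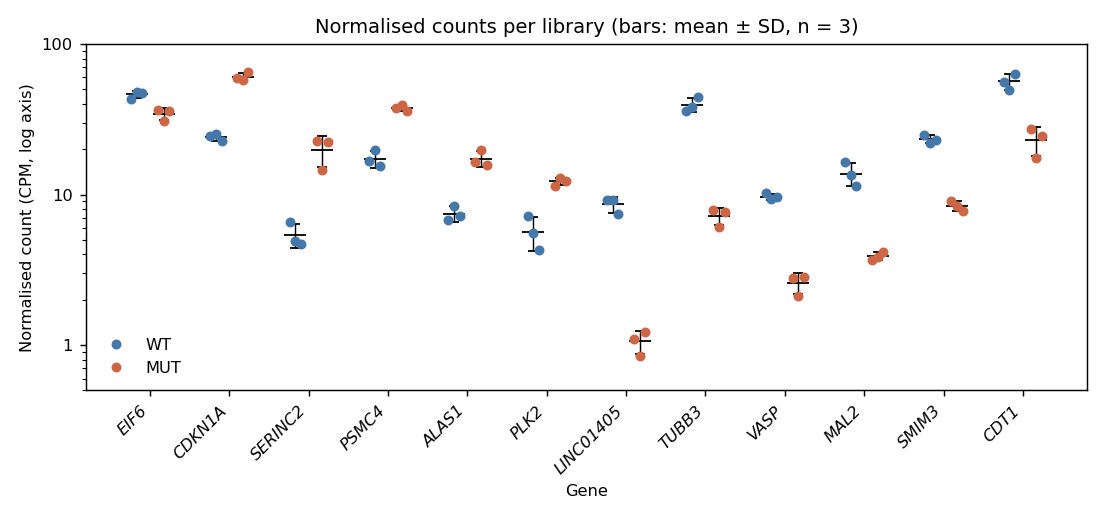
Normalised counts (CPM, log axis) of EIF6 and 11 named genes in each WT and MUT library. Points are libraries and bars the mean ± SD of 3. Apart from EIF6, whose difference did not pass the threshold, the genes shown from CDKN1A to PLK2 were higher and those from LINC01405 to CDT1 lower in MUT.

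Among the genes with the largest increases, SERINC2, of a family of serine incorporator membrane proteins, rose from 5.40 ± 1.01 CPM in WT to 19.9 ± 4.65 in MUT (n = 3 each; log2 fold change 1.88, SE 0.21, edgeR adjusted p = 0.0054). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 24.2 ± 1.33 to 60.6 ± 3.85 CPM (1.33, SE 0.12, adjusted p = 0.002). The phosphate transporter SLC20A1 (1.28), the mitochondrial ribosomal protein gene MRPL39 (1.22), ALAS1, the first enzyme of heme synthesis (1.21), and the cargo receptor TMED9 (1.17) also rose. So did the matrix proteoglycan VCAN (1.15), the proteasome ATPase PSMC4 (1.12), the polo-like kinase PLK2 (1.11), the matrix protein TINAGL1 (1.05) and the integrin ITGB4 (1.01). ST13P12 (1.75) is a pseudogene whose reads may belong to copies of ST13. These 12 genes had adjusted p-values between 0.002 and 0.0228 in edgeR's test.

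The noncoding RNA LINC01405 fell the most among named genes, from 8.60 ± 1.02 to 1.06 ± 0.19 CPM (n = 3 each; log2 fold change -3.03, SE 0.17, edgeR adjusted p = 0.000164). TUBB3, a beta-tubulin typical of neurons (chromosome 16, 89921925 to 89936097), fell from 39.4 ± 4.21 to 7.21 ± 0.96 CPM (-2.45, SE 0.15, adjusted p = 0.000274). VASP fell from 9.71 ± 0.45 to 2.59 ± 0.41 CPM (-1.91, SE 0.14, adjusted p = 0.000685). MAL2, a membrane protein of apical transport (-1.82), SMIM3 (-1.47), the calcium-binding protein gene S100A14 (-1.44), CDT1 (-1.29), the inositol phosphatase IMPA2 (-1.21), the protein kinase A subunit PRKACB (-1.21), the RNA-binding protein gene TAF15 (-1.11) and the polyamine acetyltransferase SAT1 (-1.09) fell as well. The histone gene H2BC13 (-1.32, adjusted p = 0.0455) has near-identical paralogs, so its own value is uncertain. TUBB3 and CDT1 lie near the end of the long arm of chromosome 16, where 41 of 45 tested genes with an average log2 CPM above 0 had values below 0.

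Ribosome assembly factors and ribosomal proteins had medians of opposite sign under TMM scaling. By library size alone all these medians lay above 0, but so did that of all genes (0.54). That value was above the ribosomal protein medians and below the assembly medians. Under that scaling camera still called large-subunit proteins lower (adjusted p = 8.3e-05) and 60S and 40S assembly higher (0.00995 and 0.0316). Of 35 tested factors of 60S assembly, 26 had values above 0, and 2 rose: NOC2L (0.78, edgeR adjusted p = 0.0193), a nucleolar factor, and SBDS (0.58, adjusted p = 0.0419), which acts in the release of eIF6 from the 60S subunit and shares reads with its pseudogene SBDSP1. The same 2 passed adjusted over the list alone. Camera called the list higher (median 0.23, adjusted p = 0.0062), but not with an estimated correlation (adjusted p = 0.673) and not without MUT replicate 2 (median 0.08, adjusted p = 0.101). The 40S assembly list (37 genes, 0 called, median 0.11, camera adjusted p = 0.0257) lost its call with an estimated correlation (adjusted p = 0.673) and without WT replicate 1 (0.0609), WT replicate 3 (0.0691) or MUT replicate 2 (0.182). Of 46 large-subunit ribosomal protein genes 43 had values below 0, though many share reads with pseudogenes, and 0 were called, over all genes or adjusted over the list alone. Their median was -0.30, or 0.26 by library size alone, which was below the median of all genes under that scaling. Camera's call of that list (adjusted p = 0.0111) was absent with an estimated correlation (adjusted p = 0.953), without WT replicate 2 (0.25) and without MUT replicate 3 (0.318), where the median was -0.16 each time. The small-subunit list (32 genes, median -0.26, or 0.32 by library size alone, 0 called) did not pass camera's test (adjusted p = 0.078). It was called lower by library size alone (0.00344), without WT replicate 3 (0.0073) and without MUT replicate 2 (median -0.41, 0.00048, or 0.718 with an estimated correlation). Its median was -0.11 without WT replicate 2 (0.443) and -0.12 without MUT replicate 3 (0.577).

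Other parts of the translation machinery went both ways. Both subunits of phenylalanyl-tRNA synthetase, FARSA (0.65) and FARSB (0.70), rose, and the alanyl-tRNA synthetase AARS1 (-0.63), on the long arm of chromosome 16, fell; these were the 3 called genes among 20 aminoacyl-tRNA synthetases (2 higher and 2 lower adjusted over the list alone, and without MUT replicate 2). The small nucleolar RNP protein FBL fell (-0.59, edgeR adjusted p = 0.0475; 0.02 on the log2(TPM + 1) scale), the called gene among 26 of RNA polymerase I and nucleolar RNA modification (0 called with any 1 library left out). No gene was called among 39 initiation factors, 19 factors of elongation and ribosome recycling and 9 genes listed for binding or keeping idle 80S ribosomes. Of those 9, some are not known to do so, among them SCO1 and CTIF. None of these 5 lists passed camera's test (adjusted p from 0.744 to 0.78).

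No gene of the mitotic lists was called with all 6 libraries. Among 33 genes of the anaphase-promoting complex and mitotic exit, 27 of the spindle checkpoint and kinetochore, 28 mitotic kinases and spindle factors and 21 of cytokinesis, 0 were called, with list medians of -0.03, 0.09, 0.00 and -0.01. Adjusted over the list alone, 3 checkpoint and kinetochore genes were higher and 1 cytokinesis gene was lower. Without MUT replicate 2, 1 checkpoint and kinetochore gene was called higher and 1 lower, and that list's median was -0.02. Camera's adjusted p was between 0.744 and 0.962 for these 4 lists. The G1/S and replication list was called lower by camera (39 genes, 30 below 0, median -0.16, or 0.38 by library size alone, adjusted p = 0.0335), and CDT1 was its 1 called member, over all genes and adjusted over the list alone. That call was absent with an estimated correlation (adjusted p = 0.673) and without WT replicate 2 (0.115), WT replicate 3 (0.0818), MUT replicate 1 (0.11) or MUT replicate 3 (0.07).

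Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median log2 fold change of -0.85, and 43 of 44 had values below 0. One, H2BC13, passed the test over all genes (2 genes without MUT replicate 2), and 32 were lower adjusted over the list alone. Camera called the list (adjusted p = 2.45e-14), though not with an estimated correlation (adjusted p = 0.673). Its median was -0.57 without MUT replicate 2, the library high in ribosomal RNA, and -0.37 under scaling by library size alone. The histone genes took 1.47% ± 0.14 of all counts in WT and 1.18% ± 0.11 in MUT (SD, n = 3), with no overlap, and the two-sided exact permutation test gave its smallest possible p, 0.1. Of the counts without 7SL, 7SK, RPPH1 and RMRP RNA they took 7.48% ± 1.07 in WT and 5.11% ± 1.98 in MUT, with overlap (exact permutation p = 0.2), and for shares of TPM the exact permutation p was 0.3.

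Of 30 tested targets of p53, 28 had values above 0 (median 0.36), 4 rose over all genes and 10 adjusted over the list alone; 5 rose without MUT replicate 2, 2 without WT replicate 1 and 1 without each of the others. CDKN1A and PLK2 were joined by the antiproliferative gene BTG2 (0.70, SE 0.12, edgeR adjusted p = 0.0294) and the death receptor gene FAS (1.10, SE 0.22, adjusted p = 0.0437). Camera called the list (adjusted p = 2.3e-08), also with every library left out in turn. The fry test, which asks whether the genes move one way on balance, gave an adjusted p of 0.00234. With an estimated correlation, however, camera's adjusted p was 0.0876. That estimate was -0.0068, below the preset 0.01, so a higher correlation between these genes does not account for the lost call. Among 25 apoptosis regulators, the survival gene BCL2L1 rose (0.83, adjusted p = 0.0303; 2 higher adjusted over the list alone and 2 without MUT replicate 2), and the list did not pass (camera adjusted p = 0.249).

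Camera called the Wnt and YAP/TAZ target lists higher (adjusted p = 0.0081 and 0.0067), but neither with an estimated correlation (adjusted p = 0.673 each), and 2 of 15 and 1 of 20 genes were called. Of 15 Wnt targets 12 had values above 0 (median 0.39), and the Wnt inhibitor DKK1 (0.96, SE 0.17, edgeR adjusted p = 0.0278) and cyclin D1, CCND1 (0.82, SE 0.15, adjusted p = 0.0303), rose; 4 were higher adjusted over the list alone. Of 20 YAP/TAZ targets 15 had values above 0 (median 0.29), the ectonucleotidase NT5E rose (0.94, adjusted p = 0.0192), and 4 were higher adjusted over the list alone; without MUT replicate 2, 4 were called over all genes. The Wnt call was absent without MUT replicate 1 (median 0.21, adjusted p = 0.059), and the YAP/TAZ call without WT replicate 2 (0.0569) or MUT replicate 3 (0.0645). With 1 library left out the Wnt median ran from 0.21 to 0.39 and the YAP/TAZ median from 0.17 to 0.46. Among 30 adhesion and epithelial-mesenchymal genes 4 rose and 2 fell (8 and 6 adjusted over the list alone). The integrins ITGB4 (1.01) and ITGA3 (0.79) rose, while the tight junction gene CLDN7 (-0.77) fell. That list was not called (camera adjusted p = 0.108, or 0.673 with an estimated correlation), but was without WT replicate 1 (0.0427) or WT replicate 3 (0.0066) and with the 4 libraries low in ribosomal RNA (0.0348).

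**Figure D2:**
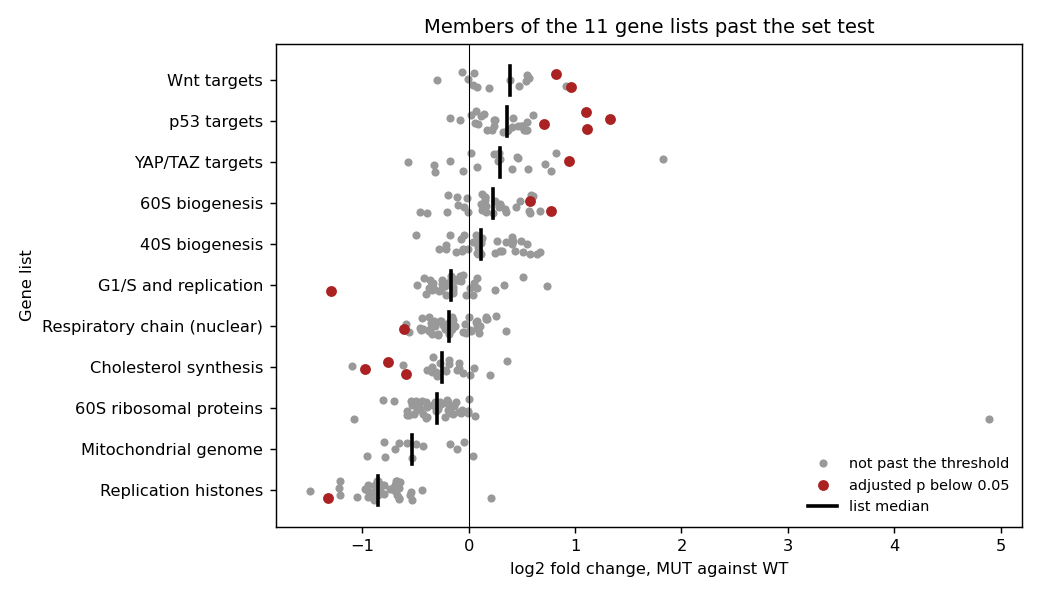
Log2 fold change, MUT against WT, of each tested member of the 11 gene lists that passed camera's test. Points are genes, red where edgeR's adjusted p was below 0.05, and black bars are list medians. Medians ran from -0.85 for replication histones to 0.39 for Wnt targets, and the ribosomal protein gene far to the right is RPL41, whose reads are shared with a pseudogene. Under scaling by library size alone the medians of the lower lists other than replication histones and mitochondrial genes lay above 0, but below the median of all genes (0.54).

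Of 24 tested cholesterol synthesis genes, 20 had values below 0 (median -0.25, or 0.29 by library size alone). MVD (-0.97), FDFT1 (-0.59) and the sterol-regulated gene INSIG1 (-0.76) fell, with edgeR adjusted p-values of 0.0228, 0.0294 and 0.0242, and 5 genes were lower adjusted over the list alone. MVD lies near the end of the long arm of chromosome 16. Camera called the list (adjusted p = 0.0016), fry did too (adjusted p = 0.0239), and with an estimated correlation camera's adjusted p was 0.249. Here too the estimate (-0.0147) lay below the preset 0.01. By library size alone camera's adjusted p was 0.0525. The desaturase SCD fell (-0.93, adjusted p = 0.0199) among 25 genes of fatty acid synthesis (1 higher and 4 lower adjusted over the list alone), a list that did not pass (camera adjusted p = 0.0687) except without WT replicate 2 (0.0423). No gene of 24 in glycolysis was called (camera adjusted p = 0.744).

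The 13 protein-coding genes of the mitochondrial genome had a median of -0.53 (-0.32 without WT replicate 1, -0.01 by library size alone and 0.09 on the log2(TPM + 1) scale), with 0 called and 5 lower adjusted over the list alone. Camera's call (adjusted p = 0.0081) was absent with an estimated correlation (adjusted p = 0.753), without WT replicate 1 (0.155) and without MUT replicate 3 (0.07). As a share of all counts they took 0.123% ± 0.044 in WT and 0.117% ± 0.039 in MUT (SD, n = 3; two-sided exact permutation p = 0.9, smallest possible 0.1), and of the counts without 7SL, 7SK, RPPH1 and RMRP RNA 0.601% ± 0.112 and 0.462% ± 0.039 (exact permutation p = 0.2). Nuclear genes of the respiratory chain were called lower (49 tested, 35 below 0, median -0.18, or 0.39 by library size alone, camera adjusted p = 0.0462), with UQCRC2 the 1 gene that fell (-0.60; 0.02 on the log2(TPM + 1) scale), over all genes and adjusted over the list alone. That call was absent with an estimated correlation (adjusted p = 0.953) and without WT replicate 2 (0.404), MUT replicate 1 (0.11) or MUT replicate 3 (0.423), and with 1 library left out the median ran from -0.28 to -0.08. Among 57 mitochondrial ribosomal protein genes MRPL39 rose and MRPL23 (-0.74) fell (2 higher and 3 lower adjusted over the list alone, 2 and 2 without MUT replicate 2), and the list was not called (camera adjusted p = 0.803).

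Stress, immune and degradation genes gave single called genes. PCK2 (-0.77) fell among 27 ATF4 targets (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.2). The NRF2 list of 21 held the transketolase TKT (-0.78; 3 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.29), and the autophagy and lysosome list of 33 held GABARAPL2 (-0.77, on the long arm of chromosome 16; 7 higher and 3 lower adjusted over the list alone). The latter list had a median of 0.19 and a camera adjusted p of 0.0504, or 0.673 with an estimated correlation. It passed without WT replicate 2 (0.0415) and with DESeq2's size factors in edgeR (0.0486). IL32 (-2.33) fell among 15 inflammatory genes (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.423) and the immunoproteasome gene PSMB9 (-1.57) among 13 of antigen presentation (3 higher and 2 lower; 0.744). No gene was called among 22 interferon-stimulated genes, 23 endoplasmic reticulum chaperones, 15 heat shock genes, 18 immediate early genes, 19 hypoxia genes, 29 MYC targets and 5 colon differentiation markers, and camera's adjusted p for these lists was between 0.2 and 0.873. Adjusted over the list alone, 3 interferon-stimulated genes were higher and 3 lower, 2 chaperones and 1 immediate early gene higher, 2 MYC targets lower, and 2 colon markers higher and 2 lower. With the 4 libraries low in ribosomal RNA alone, camera called the immediate early list higher (median 0.24, against -0.09 with all 6 libraries; adjusted p = 7.62e-05), and 2 of its genes were called higher without MUT replicate 2, where camera's adjusted p with an estimated correlation was 0.767. Camera also called that list in 3 of the 9 other splits of the 6 libraries. Without MUT replicate 2, 2 ATF4 targets were called lower, and 3 NRF2 genes, 1 autophagy and lysosome gene and 2 antigen presentation genes higher. The lists for fibroblasts, leukocytes, endothelial and erythroid cells and other epithelial cells had 4, 1, 3 and 2 tested members, of which 0 were called.

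By chromosome, camera called 0 of 23 at an adjusted p of 0.05, and 1, chromosome 16, had an unadjusted p below 0.05 (p = 0.0024, adjusted 0.0563; adjusted p = 0.765 with an estimated correlation). Of its 701 tested genes 26 fell and 4 rose, and its median log2 fold change was -0.11. Chromosome 16 passed without WT replicate 2 (adjusted p = 0.0386) or MUT replicate 3 (0.0359), and camera's adjusted p was 0.411 without MUT replicate 2.

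**Figure D3:**
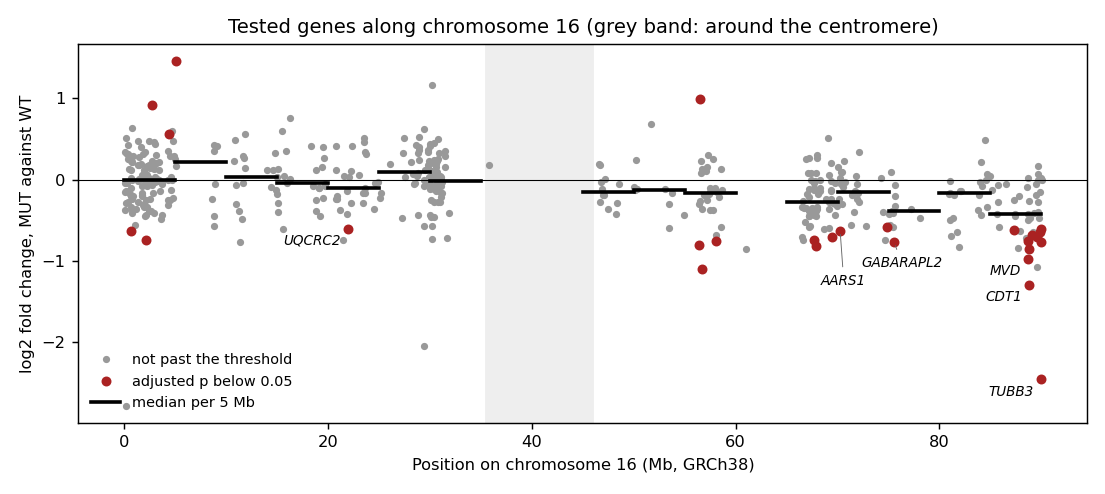
Log2 fold change, MUT against WT, of tested genes with an average log2 CPM above 0 along chromosome 16 (Mb, GRCh38). Points are genes, red where edgeR's adjusted p was below 0.05, and black bars are medians over windows of 5 Mb. Beyond 85 Mb the median was -0.43, and 11 genes were called lower and 0 higher.

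Among the abundant noncoding RNAs, the share of RPPH1, the RNA of ribonuclease P, was 5.36% ± 0.36 of all counts in WT and 8.59% ± 0.87 in MUT (SD, n = 3), without overlap (two-sided exact permutation p = 0.1, the smallest possible). After TMM scaling, its log2 fold change was 0.19 (SE 0.52, edgeR adjusted p = 0.891). RMRP, of the related ribonuclease MRP, took 1.37% ± 0.22 in WT and 1.14% ± 0.01 in MUT (exact permutation p = 0.1, again the smallest possible). After TMM scaling, the log2 fold change of RMRP was -0.80 (SE 0.43, edgeR adjusted p = 0.343). Ribosomal protein genes took 5.17% ± 2.12 and 6.04% ± 2.79 (exact permutation p = 0.7), and the 20 most abundant genes 83.2% ± 4.68 and 78.8% ± 8.31 (exact permutation p = 0.5), and both differences changed sign without MUT replicate 2. Of the counts without 7SL, 7SK, RPPH1 and RMRP RNA, ribosomal protein genes took 25.0% ± 3.98 in WT and 23.2% ± 1.55 in MUT (exact permutation p = 0.7).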

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

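The tests added after seeing the data were the term for the 2 libraries high in ribosomal RNA, the fit on the other 4, the removal of abundant RNAs and the splits of the libraries. Against 283 genes called and 105 over 2-fold, counts stayed within 1.5 times with DESeq2's size factors in edgeR (284), limma-voom (262), the added term (407), the other 4 libraries (395) and abundant RNAs removed (312). They were 108 called with library size alone (54 shared), 462 with at least 1 CPM, 552 and 158 over 2-fold with the robust fit, 1195 and 408 with no low-count filter, and 760 and 200 with DESeq2, which shared 282 with the 283. On limma's log scales, where fewer genes were tested, they were 21 and 20 for log2(TPM + 1), 10 and 9 for log2(TPM + 0.1), and 13 and 12 for log2(FPKM + 1). The cause was not tested for these or the differences below. Leaving out 1 library gave 27 to 442 genes and 25 to 149 over 2-fold. Of the 50 genes that the naming rule takes besides EIF6, 12 kept direction and call with library size alone, 15 to 49 with 1 library left out, and 45 to 50 under the other settings that used counts (49 of 49 with at least 1 CPM). On the TPM and FPKM scales 3 of 27, 2 of 27 and 3 of 46 did. FBL turned to 0.0194 and 0.0200 and UQCRC2 to 0.0191 and 0.0143 on the 2 TPM scales. The median of all genes moved to 0.54 with library size alone, 0.36 and 0.49 on the TPM scales and 0.33 on the FPKM scale. EIF6 passed only in DESeq2 (-0.414) and ranged from -0.479 to -0.332 with 1 library left out.

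Of 38 gene lists, 11 were called, and 6 to 11 with 1 library left out. Of the 26 lists with enough members on the TPM scales, 2 were called on each (p53 targets and replication histones). On the FPKM scale 8 of 36 were called. The fry test called 2 of 38, and camera with an estimated correlation 0 (smallest adjusted p = 0.0876, and 2 at an unadjusted p below 0.05). Chromosomes called were 0, or 1 without WT replicate 2 or MUT replicate 3 (0 to 1 over the left-out libraries).

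The replicate numbers gave no clear sign of pairing: deviations of same-numbered libraries from their group means correlated at -0.291, -0.0414 and 0.219, and not every sample correlated best with its own number. With few libraries per group, and MUT replicate 2 dominating the MUT deviations, these correlations cannot exclude pairing. With the replicate number as a block 296 genes were called, 225 shared, and 10 lists. The 3 libraries per group limit what can be seen: at 2-fold, 30.9% of simulated changes were called. Of the 10 splits of the 6 libraries into 3 and 3, too few for a share below 0.05, 1 (the real one) gave as many genes (283 called, highest other 1; 105 over 2-fold, highest other 1), 3 gave as many gene lists (11, highest other 13), and all 10 gave as many chromosomes (0, highest other 0).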

Other observations

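Of the tests below, those of the position and the copies of the chromosome 16 region, and those of MUT replicate 2 and of S phase as sources of the lower histone values, were chosen after the values they use had been seen. The genes in the next 2 paragraphs that the naming rule did not take were also chosen after their values were seen.

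The growth factor BMP4 fell from 21.5 ± 2.46 to 10.4 ± 0.31 CPM (n = 3 each; log2 fold change -1.05, SE 0.12, edgeR adjusted p = 0.0066), and ID3, a gene that BMP signalling raises, from 79.8 ± 12.3 to 41.6 ± 4.79 CPM (-0.94, SE 0.16, adjusted p = 0.0264). The epithelial transcription factor ELF3 (-0.94) and the tight junction gene CLDN4 (-0.94) fell, and the EGFR ligand AREG (0.90) and the crosslinking enzyme TGM2 (1.80) rose. A lower response to BMP may account for ID3, but in a test stated beforehand, 6 other BMP response genes had a median of -0.18 (SE 0.31), 3 of 6 were below 0, and 0 were called, which leaves this open.

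Around EIF6, 42 other genes were tested within 1.5 Mb on either side, and 3 rose, 0 fell: PIGU (1.51, SE 0.15, edgeR adjusted p = 0.003; chromosome 20, 34560542 to 34677092), UQCC1 (0.56, adjusted p = 0.0371; 35302578 to 35411973) and EPB41L1 (0.85, adjusted p = 0.0287). The median of all 42 was -0.11.

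Genes at the end of the long arm of chromosome 16 (from 85 Mb) were lower in MUT: 41 of 45 tested genes with an average log2 CPM above 0 had values below 0, 11 were called lower, among them TUBB3, CDT1 and MVD, and the median was -0.43 (-0.34 without MUT replicate 2). Over the chromosome 26 of all 701 tested genes were called lower against 105 of 13969 elsewhere (Fisher's exact test, which takes genes as independent, adjusted p = 2.23e-08 over 46 tests). A scatter of the fold changes without regard to position is argued against. Of 1000 random reassignments of the fold changes, 0 held a run of 45 genes as far from 0 (largest 0.34), a share of at most 0.1%, the smallest they can give. The reassignments break any likeness between neighbouring genes, so they cannot exclude a chance run that arises from it. In the real data 8 of 1774 runs elsewhere lay as far from 0, the largest with a median of 0.84 in size. These runs started every 5 genes and so overlapped, and the 8 may come from fewer places. GC content is argued against as the whole source, since the median was -0.45 (SE 0.07) after removal of the GC trend. Fewer copies of the region in the mutant cells may explain it and cannot be told apart from regulation without DNA data: the uncalled genes had a median of -0.28 (SE 0.08), the rest of the long arm -0.19 and the short arm 0.00.

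MUT replicate 2 stood apart from the other libraries. Reads given to other near-identical copies may be part of it. Genes with a pseudogene named after them and all pseudogenes were left out. So were histone genes, ribosomal RNA, small noncoding RNA families, LOC symbols and symbols with a hyphen, which left 10469 genes. That removes more than genes with a near-identical copy, so the change may also have other sources. The mean correlation of MUT replicate 2 with the other MUT libraries went from 0.942 to 0.966, against 0.977 between those. After removal of trends on transcript GC and length it was 0.972 against 0.978. The gaps were 0.0109 (SE 0.0013) and 0.0062 (SE 0.00083). These SEs are over resampled genes and hold no spread between libraries. Neither gap fell within or clearly beyond the bounds set beforehand, so neither source can be excluded or taken as the whole. No biological explanation was tested.

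Of 44 replication histones 43 had values below 0, but 1 was called, and camera's call of the list was absent with an estimated correlation (adjusted p = 0.673) and present in 5 of the 9 other splits of the 6 libraries. MUT replicate 2 alone may account for the lower values and is left open: the list's median was -0.57 without it, with an SE between libraries of 0.26, too wide to settle this. Less RNA without a poly(A) tail in the MUT libraries may contribute and cannot be told apart: 100 other such RNAs had a median of -0.37 (SE between libraries 0.31), between the bounds set beforehand. Fewer cells in S phase may contribute too: the G1/S and replication list had a median of -0.16 (SE 0.04), but its call was absent with an estimated correlation.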
